A study of Mus musculus with 8 samples.

How the data were processed

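RNA was measured in 8 mouse libraries: cerebellum, cortex, hippocampus, glia and neuron of strain C57, embryonic fibroblasts of strains ICR and OG2, and the library labelled R1 ESC. Per the labels, total RNA was taken up in Trizol and libraries were made from 1 ug with the Illumina TruSeq RNA kit; the submitters' processing notes name Bowtie and RSEM, without versions, and the build mm10. The annotation release and the strandedness of the libraries are not given in the sources used here, nor are the age and sex of the animals or the way neurons and glia were isolated. Expected counts per gene, as RSEM estimates them, were deposited for each library, per the file headers. TPM values, scaled by effective length, were deposited by the authors in the same tables, as were effective lengths in bases, per the file headers. The tables held 29713 genes, of which 29202 had a symbol and 511 an identifier alone; identifiers without a symbol took 0.0944% to 0.248% of the counts. Reads were not mapped again here, and mitochondrial genes were not analysed here. Some genes that met the rule for named genes are not reported here.

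Of the TPM values at 10 or more, 99.9% were recomputed from the expected counts and effective lengths to within 1%, and 88.9% of the expected counts were whole. Total expected counts ran from 2147004 to 5864673 per library, at which 3 counts on a gene of 2000 bases are worth 0.461 to 0.943 TPM. Gene coordinates were taken from GENCODE release M21 (GRCm38, mm10) by the gene identifiers of the deposited tables. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors alone.

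Each group held 1 library, so no test across libraries was run. The 9 comparisons were neuron with glia, each of 3 brain regions with the other 2, the library labelled R1 ESC with both MEF libraries, ICR MEF with OG2 MEF, the brain regions with the non-neural libraries, and neuron and glia each with the brain regions. A gene was called when every library of the higher side had at least 10 TPM and the lowest of that side was at least 4-fold above the highest of the other on TPM with 1 added. The log2 ratio given for a gene is that between those libraries. Folds were also computed on TPM without the added 1, with exact (Clopper-Pearson) 95% intervals, and a side at 0 counts was set to 3 counts per library. The 43 gene lists (42 with measured genes, 474 distinct genes) were summarised by the number of genes called and by the median difference of the groups' mean log2(TPM + 1) over members with a mean TPM of at least 1, set against 10000 random lists of such genes matched in 20 bins of expression, with seed 11. Named genes are the 10 with the largest log2 ratio per direction for neuron with glia, cerebellum, the library labelled R1 ESC with the MEFs, and brain with non-neural libraries, and 5 per direction elsewhere, leaving out predicted gene models, ribosomal and small RNA genes. Genes of a list are given as its examples. The comparisons, the calling rule, the lists, the rule for named genes and the first 7 alternatives were chosen before the data were examined.

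Alternatives fixed in advance were 0.1 or 5 TPM added in place of 1, a floor of 1 TPM, TMM factors of the counts applied to TPM, counts scaled to the library total with no length term (CPM), TPM rescaled without haemoglobin genes, and counts thinned to 2146964 per library. Each comparison with more than 1 library on a side was also run without each of them. TMM factors of the TPM, and removal of the trend of the log2 ratio with length in 20 bins, were added after seeing the data. Both bring the libraries to a common level by construction. The calling rule was tested on simulated data: of 100 genes set 8-fold apart, 99 were called for neuron with glia, 99 for the library labelled R1 ESC with the MEFs and 100 for cerebellum, and of 100 set 2-fold apart 0. Among the unchanged genes of the same runs, each of 29713 genes in all, 12, 5 and 1 were called. Simulated libraries were drawn from 1 measured library and its effective lengths with counting error only. Variation between animals or preparations, length effects and shared reads are not covered. Of 100 simulated lists of 12 unchanged genes, 0, 2 and 3 lay outside percentiles 2.5 to 97.5 of the random lists, and all 20 lists set 2-fold higher lay above in each.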

Results

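RNA sequencing was carried out on 8 mouse libraries, 1 in each of 8 groups. Cerebellum, cortex and hippocampus were brain regions of strain C57, and the glia and neuron libraries came from brain of the same strain. ICR MEF and OG2 MEF were embryonic fibroblasts from day 13.5 embryos of strains ICR and OG2. The remaining library was labelled R1 ESC, an embryonic stem cell line derived from the inner cell mass of a 129X1 x 129S1 embryo. Total expected counts ranged from 2147004 in the library labelled R1 ESC to 5864673 in glia. They were 5572116 in cerebellum, 5369399 in cortex, 3686772 in hippocampus, 3983575 in neuron, 4805982 in ICR MEF and 5404041 in OG2 MEF. The number of genes at 10 TPM or more lay between 10481 and 10664 in the brain regions. It was 10013 in glia, 8497 in ICR MEF, 8152 in OG2 MEF, 7369 in neuron and 4132 in the library labelled R1 ESC. With 1 library per group no difference between groups has a replicate check, and no p-value is given.

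The libraries differed in composition. Ribosomal protein genes took 49.2% of TPM in the library labelled R1 ESC, 20.8% in OG2 MEF, 19.9% in ICR MEF and 17.7% in neuron, against 7.36% in glia and between 4.56% and 5.59% in the brain regions. The mean effective length behind a count was 1739 bases in the library labelled R1 ESC and 2488 bases in neuron, and 3729.8 to 3739.7 bases in the brain regions. Across 12646 protein-coding genes, which are not independent replicates, Spearman's rho was 0.982 between the MEF libraries, 0.961 between cortex and hippocampus and 0.847 between cerebellum and cortex. Glia was closer to ICR MEF (0.798) than to cerebellum (0.551), hippocampus (0.533), cortex (0.527) or neuron (0.494).

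A gene counted as higher or lower when every library of the higher side reached 10 TPM and the lowest of them was at least 4-fold above the highest library of the other side on the TPM + 1 scale. Folds are ratios of TPM between those same libraries, with exact (Clopper-Pearson) 95% intervals from the expected counts. Where the other side had 0 counts, the fold is a lower bound with each such library set at 3 counts. Intervals and bounds cover counting error only. List medians, and the median of all genes, compare the groups' means of log2(TPM + 1), the latter over genes with a mean of at least 10 TPM in the libraries compared.

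**Figure D1:**
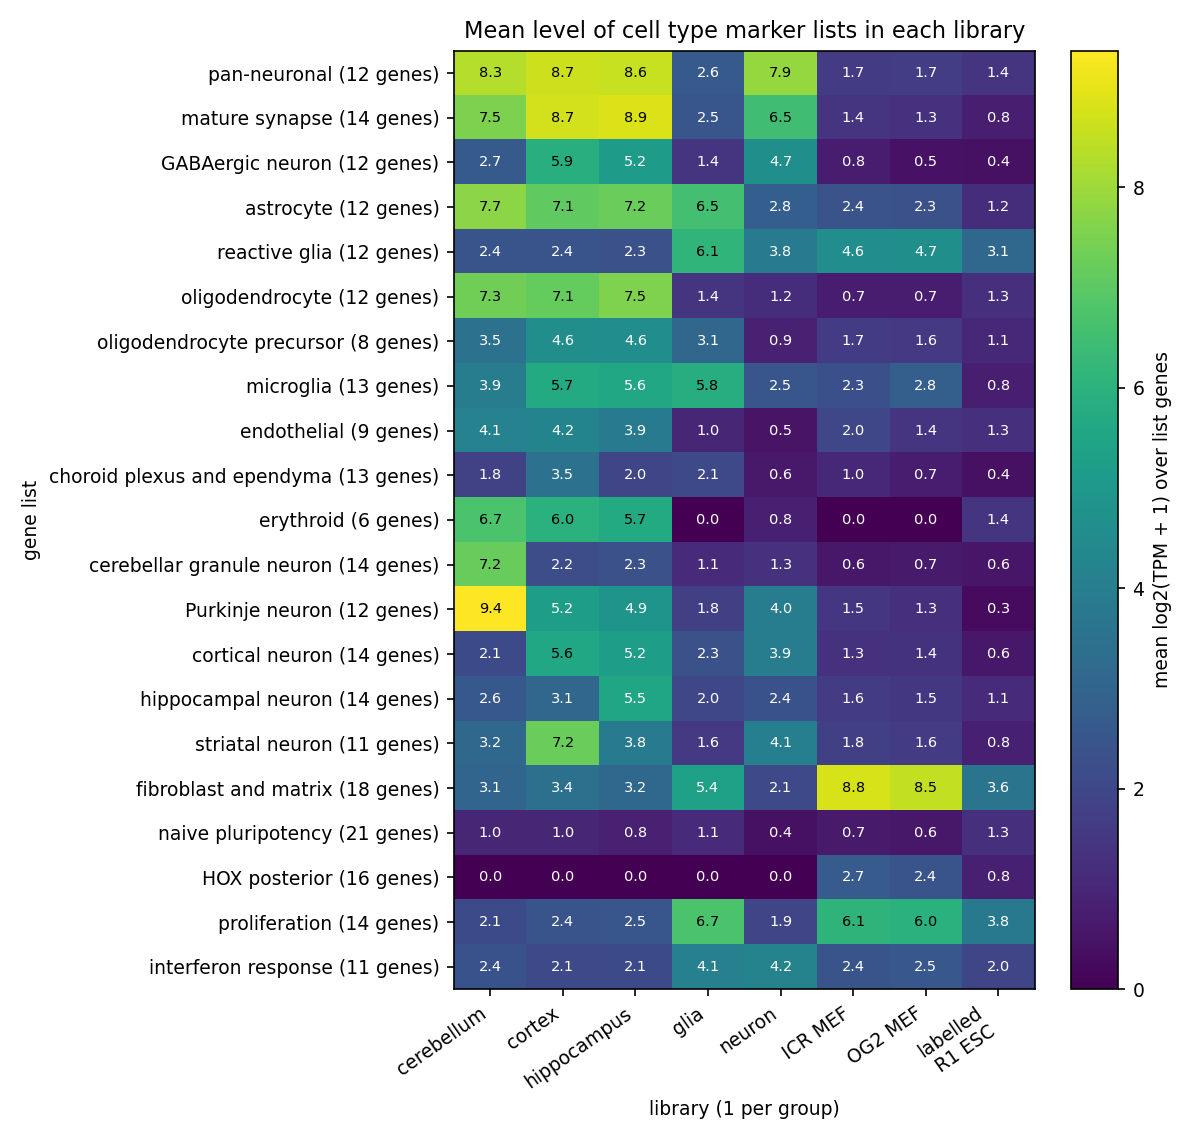
Mean log2(TPM + 1) of the genes of each list (vertical axis) in each of the 8 libraries (horizontal axis, 1 library per group), as colour and as printed value. The pan-neuronal list stood at 7.9 to 8.7 in neuron and the brain regions and at 2.6 in glia, and the fibroblast and matrix list at 8.8 and 8.5 in the MEF libraries and 3.6 in the library labelled R1 ESC.

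**Figure D2:**
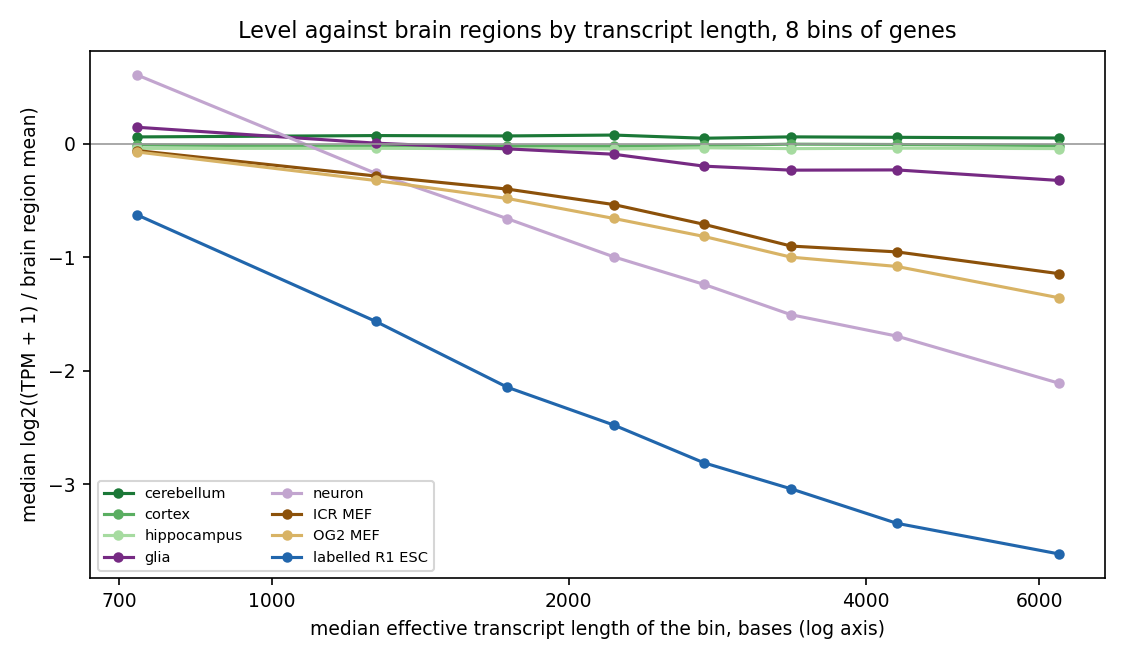
Median log2 ratio of TPM to the mean of the brain regions (vertical axis) in 8 bins of effective length (horizontal axis, bases) for the 8 libraries, 1 library per group. In the longest bin the medians were -0.33 in glia, -1.15 in ICR MEF, -1.36 in OG2 MEF, -2.11 in neuron and -3.61 in the library labelled R1 ESC.

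Neuron and glia, the isolated preparations from brain, were separated by genes of neuronal signalling on one side and by contractile, matrix and cell cycle genes on the other: 1163 genes were higher and 3412 lower in neuron. Somatostatin (Sst, ENSMUSG00000004366, chromosome 16, 23889573 to 23890958, mm10), a neuropeptide of inhibitory interneurons, stood at 1080.3 TPM in neuron and 0 in glia, at least 412-fold higher. Stmn4, a stathmin-family regulator of microtubules (ENSMUSG00000022044, chromosome 14, 66344296 to 66361680), was 2225-fold (615 to 18363) higher, neurogranin (Nrgn) 1815-fold (620.2 to 8797), and beta-synuclein (Sncb) at least 449-fold. Caly, Gng13, Lin7b, Fxyd7 and the neuropeptide gene Cck were also among the leading higher genes, with log2 ratios from 8.63 to 9.70. On the other side smooth muscle actin (Acta2, ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) reached 4147 TPM in glia and 7.6 in neuron, 546-fold (398 to 772) lower, followed by the matrix protein gene Thbs1 (-8.33), moesin (Msn, -8.21), Ccn2 (-8.19), Tagln (-7.96), Fmod (-7.92) and Palld (-7.80).

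Of the 12 measured pan-neuronal genes 11 were higher in neuron, among them Snap25 at 446 against 0.73 TPM, Syp at 906 against 10.1 and Rbfox3 at 85.96 against 0. The list's median log2 ratio of 5.45 lay 6.28 above the median of all genes. Of the mature synapse genes 11 of 14 were higher, of the glutamatergic forebrain genes 7 of 10 (Slc17a7, 173 against 0.64 TPM). Of the GABAergic genes 6 of 12 were higher (Gad1, 63.8 against 0.99) and 1 was lower, which was 0 with CPM, TMM factors of the TPM or the length trend removed. Among 12 brain splicing regulators 6 were higher, with Celf4 at 184 against 6.97 TPM. Immediate early genes, which respond to activity and to handling of tissue, were higher for 5 of 12 (Egr4, 65.4 against 0.18 TPM), and Dusp1 was lower, though not under those 3 scalings. The medians of these 6 lists lay at percentile 100 of 10000 matched random lists, a description of these libraries.

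Astrocyte, microglia and dividing-cell genes ran the other way, while of 12 oligodendrocyte genes 1 was lower (median -0.48, percentile 68.4). Of 12 astrocyte genes 8 were lower in neuron and none higher (Gfap, 20.2 against 1492 TPM; Aqp4, 2.24 against 231), with a median of -4.60, and of 13 microglia genes 10 were lower (Ctss, 2.44 against 158). The reactive glia list split: 6 of 12 were lower, led by vimentin (Vim) at 105 against 10414 TPM, while the acute-phase gene Lcn2 was higher at 277 against 5.40. Proliferation genes were lower for 13 of 14 (Top2a, 4.38 against 262 TPM; Cdk1, 1.13 against 288), p53 and senescence genes for 8 of 10 and fibroblast and matrix genes for 12 of 18 (Fn1, 8.63 against 1018). With CPM or TMM factors of the TPM 5 p53 and senescence genes were lower. Under 3 of the other scalings (CPM, TMM factors of the TPM, length trend removed) 1 gene of the fibroblast and matrix list was higher. The medians of the astrocyte, microglia, reactive glia, proliferation, p53 and senescence and fibroblast and matrix lists lay at or under percentile 0.20 of the random lists.

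The median log2 ratio of all genes was -0.83 on the TPM scale, -0.62 with TMM factors of the counts, -0.20 with CPM and -0.02 both with TMM factors of the TPM and with the length trend removed. The share of lower genes fell from 74.6% to 60.6% with CPM and 51.6% with either of the last 2. These last 2 settings bring the libraries to a common level by construction, so their values do not show why more genes were lower. Reads of Hist2h2aa2 and Elobl, both among the 10 leading lower genes, can be shared with near-identical copies. Xist (log2 ratio 8.80) had different effective lengths in the libraries. The values of these genes are therefore uncertain. As the sex of the animals is not given, the Xist difference also cannot be told apart from one of sex.

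Cerebellum differed from cortex and hippocampus by 264 higher and 353 lower genes, and the leading ones were markers of its granule and Purkinje neurons. Pcp2, a Purkinje cell protein (ENSMUSG00000004630, chromosome 8, 3623371 to 3625545), stood at 1507 TPM in cerebellum, 1.73 in cortex and 2.61 in hippocampus, 578-fold (175 to 5230.4) higher. Gabra6, the GABA-A receptor subunit of granule cells (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072), was 724-fold (282 to 2655) higher, Cbln3 356-fold (216 to 637), Ppp1r17 786-fold (139 to 30745), Cnpy1 327-fold (158 to 813) and Crtam at least 129-fold. Car8 at 1016 TPM and the cadherin gene Fat2 at 132 followed. Iltifb, which has a near-identical copy, and Lhx1os, which lies antisense to Lhx1, completed the 10 leading genes and are uncertain.

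Of 14 granule neuron genes 12 were higher (Zic1, 566 TPM against 9.17 and 15.7; En2, 101 against 0.26 and 0.19), and of 12 Purkinje neuron genes 10 (Pvalb, 1332 against 76.6 and 72.9; Calb1, 916 against 160.3 and 128). Their medians of 4.55 and 3.65 both lay at percentile 100 of the random lists. Eomes, a transcription factor of unipolar brush cells, was higher at 39.1 TPM against 0.64 and 1.30.

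Forebrain genes were lower in cerebellum: 10 of 14 cortical neuron genes (Emx1, 0 TPM against 19.7 and 17.4; Tbr1, 0.66 against 57.7 and 23.7). So were 5 of 10 glutamatergic forebrain genes (Camk2a, 59.6 against 1822 and 2477) and 5 of 12 GABAergic genes (among them Dlx1, Lhx6, Sst and Vip), with no member of the 3 lists higher. Gad1, the GABA-synthesising enzyme that Purkinje cells also use, stood at 551, 369 and 292 TPM in cerebellum, cortex and hippocampus. The largest single falls were those of Nrgn (ENSMUSG00000053310, chromosome 9, 37544492 to 37552904), 511-fold (247 to 1271) lower, the dendritic protein gene Ddn, 624-fold (357 to 1208), and Crym, at least 257-fold. They were followed by Sst (-6.98), Icam5 (-6.73), Gda (-6.46), Camkv (-6.29), Chrm1 (-6.18), Rtn4rl2 (-6.10) and Cpne7 (-5.99). The immediate early genes Junb, Egr2, Egr4 and Arc were lower too, 4 of 12 in that list. Lists of other cell types moved as well: the median was -1.68 for microglia (percentile 0) and -0.94 for oligodendrocyte precursor genes (0.27), against 0.69 for astrocyte (99.98) and 0.93 for erythroid genes (99.75). Without hippocampus the count of lower genes was 564. For a library set against 2 others, chance puts it outside their range for 66.7% of genes before the 4-fold and 10 TPM requirements, and the same holds for the other regions.

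**Figure D3:**
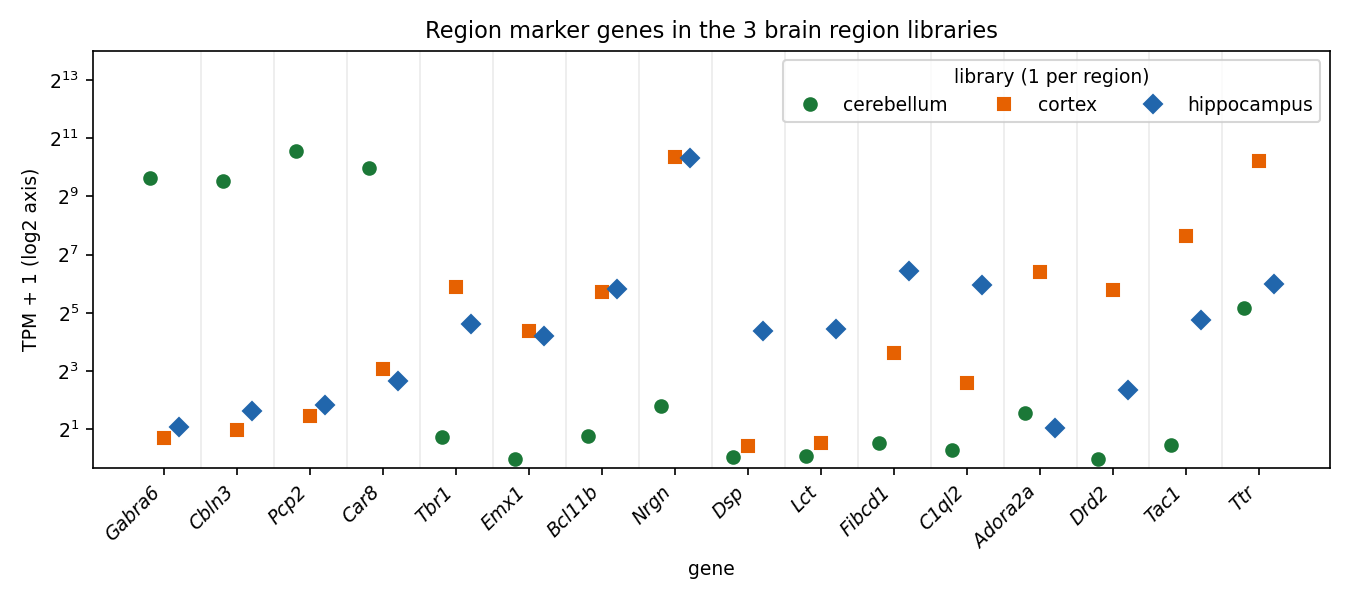
TPM + 1 on a log2 axis (vertical) of 16 region marker genes (horizontal) in the cerebellum, cortex and hippocampus libraries, 1 library per region. Gabra6, Cbln3, Pcp2 and Car8 were at 796, 741, 1507 and 1016 TPM in cerebellum, and Adora2a, Drd2, Tac1 and Ttr at 84.8, 54.1, 199 and 1183 TPM in cortex.

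Cortex had 57 higher and 7 lower genes against cerebellum and hippocampus, and the higher ones were led by genes of striatal projection neurons and of the choroid plexus. Adora2a, an adenosine receptor gene abundant in striatum (ENSMUSG00000020178, chromosome 10, 75316877 to 75334784), stood at 84.8 TPM against 1.07 in hippocampus and 1.94 in cerebellum, 43.7-fold (24.2 to 88.2) higher. Of 11 striatal neuron genes 7 were higher, with the dopamine receptor genes Drd1 at 53.8 TPM against 3.95 in hippocampus and Drd2 at 54.1 against 4.14, both at 0 in cerebellum. The list's median of 3.95 lay at percentile 100. Ttr, the thyroxine carrier secreted by choroid plexus (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), was 18.7-fold (15.4 to 23.00) higher at 1183 TPM, and Folr1 and Kcnj13 of the same list were also higher, 3 of 13 in all. Dlx5 was the only GABAergic gene higher (11.5 TPM against 0 and 2.03), and it was not with CPM, TMM factors of the TPM or the length trend removed. Cd4 was at least 12.2-fold higher. No cortical neuron gene was called: Emx1 stood at 19.7 TPM in cortex and 17.4 in hippocampus, Bcl11b at 51.7 and 55.3, and Tbr1 at 57.7 and 23.7. The cortical neuron list had a median of 2.03, percentile 100, which was 0.27 without cerebellum and 4.14 without hippocampus. Among the lower genes Il16 was 10.2-fold (6.63 to 16.1) and St18 5.32-fold (3.84 to 7.53) lower. Snhg9 and Rexo5 also met the rule, Snhg9 on 1 count and Rexo5 on at most 13 counts in each region, and are uncertain. With 5 TPM added in place of 1, St18, Snhg9 and Rexo5 fell under 4-fold. Without cerebellum the counts were 92 higher and 50 lower, and without hippocampus 564 and 341.

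Hippocampus had 35 higher and 14 lower genes against cerebellum and cortex. Of 14 hippocampal neuron genes 6 were higher and none lower, with a median of 2.31 at percentile 100; with the length trend removed 4 were. Desmoplakin (Dsp, ENSMUSG00000054889, chromosome 13, 38151294 to 38198577), a dentate granule cell marker, stood at 20.04 TPM, 57.3-fold (26.3 to 159) higher, followed by Lct (47.5-fold, 21.6 to 132) and C1ql2 (12.2-fold, 7.76 to 20.3). Spink8 and Fibcd1 of the same list stood at 72.9 and 84.8 TPM. Neurod6, a transcription factor of forebrain excitatory neurons, was higher at 224 TPM against 36.5 in cortex and 10.5 in cerebellum. Of the 11 striatal neuron genes Penk, Ppp1r1b and Syndig1l were lower (Penk, ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, 5.55-fold, 4.46 to 6.97), and the list's median of -1.26 was 1.02 without cortex and -3.42 without cerebellum. Atp6ap1l was at least 3.14-fold lower, Nexn 18.5-fold (6.10 to 91.2), the serine protease gene Klk6 11.01-fold (2.75 to 96.00) and the cadherin gene Cdh7 5.89-fold (3.74 to 9.77). Hist1h2bg was called on 5 counts and belongs to a family of near-identical histone genes. With 5 TPM added in place of 1, it, Atp6ap1l, Nexn, Klk6 and Cdh7 fell under 4-fold. Without cortex the counts were 497 higher and 376 lower, and without cerebellum 92 were lower.

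The library labelled R1 ESC held few transcripts of the naive pluripotency list. Pou5f1 stood at 20.2 TPM (71 counts), Nanog at 10.3 (55 counts) and Tdh at 14.6 (73 counts). These 3 of 21 measured members were higher than in both MEF libraries, where none exceeded 0.34 TPM. Sox2 was at 4.80 TPM, Sall4 at 2.32 and Fgf4 at 1.68, while Zfp42, Esrrb, Utf1, Dppa2, Dppa3, Dppa4, Dppa5a, Lin28a and Prdm14 had 0 counts, and Klf2 was lower than in the MEFs at 0.41 TPM, though not with the length trend removed. In all, 12 of the 21 had at most 3 counts. Over the 7 members with a mean of at least 1 TPM, the median log2 ratio to the MEFs was 1.94. Members near 0 in the MEFs enter that median only by their level in this library, so its percentile is not given. Fibroblast transcripts were present: Sparc at 302 TPM, Col1a1 at 69.2 and Fn1 at 41.1.

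**Figure D4:**
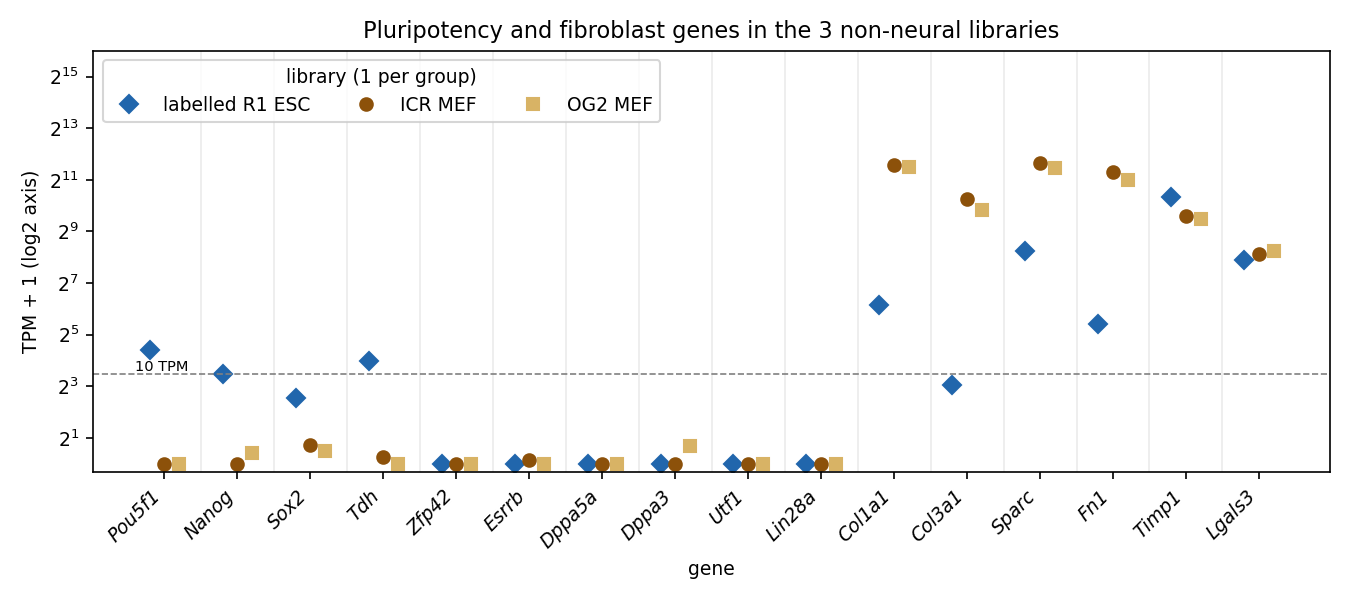
TPM + 1 on a log2 axis (vertical) of 10 pluripotency genes and 6 genes expressed in fibroblasts (horizontal) in the library labelled R1 ESC and the ICR MEF and OG2 MEF libraries, 1 library per group; the dashed line marks 10 TPM. Pou5f1, Nanog and Tdh were at 20.2, 10.3 and 14.6 TPM in the library labelled R1 ESC, and Timp1 was at 1304 TPM there against 771 and 718.

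Against both MEF libraries, 409 genes were higher and 4064 lower in the library labelled R1 ESC, directions that rest on a library with few pluripotency transcripts. Aldh3a1, an aldehyde dehydrogenase abundant in corneal epithelium (ENSMUSG00000019102, chromosome 11, 61207537 to 61218421), stood at 405 TPM, at least 413-fold higher. Nccrp1 (ENSMUSG00000047586, chromosome 7, 28543596 to 28547254) was at least 206-fold higher, the cornified envelope gene Cnfn at least 53.9-fold and the secreted protein gene Wfdc2 198-fold (54.3 to 1638). Of the epithelial list Krt8 was higher at 36.9 TPM against 4.19 and 1.13. Pcsk1n, Alpk2, Adap1, Unc13d and Sag followed with log2 ratios from 5.43 to 5.95. Expected counts of Alpk2, Unc13d and Sag were not whole, so some of their reads were shared with other genes and their values are uncertain.

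Every one of the 18 fibroblast and matrix genes was lower (Col1a1, 69.2 TPM against 3058 and 2853; Lox, 4.41 against 1232 and 1034), with a median of -5.35, -3.36 from the median of all genes and at percentile 0. Under the other scalings 13 to 18 were lower. Imprinted genes were lower for 15 of 24 and none was higher, with a median of -4.59; with CPM 1 was higher. Igf2, the fetal growth factor (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), stood at 2.16 TPM against 2266 and 3089.8, 1049-fold (587 to 2107) lower, the non-coding H19 was 301-fold (246 to 372) lower and Rian 225-fold (139.6 to 398). Thbs1 (-9.00), the chemokine gene Cxcl12 (-8.68), Igfbp7 (-8.39), Lox (-7.58), vinculin (Vcl, -7.47) and the basement membrane gene Nid1 (-7.37) were among the 10 leading lower genes, as was Dynlt1b, which shares reads with near-identical copies. Proliferation genes were lower for 6 of 14 (3 with TMM factors of the TPM and 2 with the length trend removed), but their median of -2.03 lay -0.04 from that of all genes, at percentile 28.01.

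The median log2 ratio of all genes was -1.99 on the TPM scale, -1.34 with TMM factors of the counts, -0.99 with CPM, -0.31 with TMM factors of the TPM and -0.37 with the length trend removed. The share of lower genes fell from 90.9% to 80.2%, 77.3%, 50.6% and 44.7% in the same order, and chance puts 1 library outside the range of 2 others for 66.7% of genes. TMM factors of the TPM and removal of the length trend even these shares largely by construction.

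The MEF libraries of strains ICR and OG2 were the closest pair: 38 genes were higher and 13 lower in ICR MEF, 99.6% of genes with a mean of at least 10 TPM lay within 4-fold and the log2 ratios had an SD of 0.40 across genes. Pianp, a neuronal transmembrane protein gene (ENSMUSG00000030329, chromosome 6, 124996694 to 125003096), stood at 17.1 TPM in ICR MEF and 0.58 in OG2 MEF, 29.5-fold (7.90 to 246) higher. Serpina3n, an acute-phase protease inhibitor gene (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), was 5.62-fold (3.26 to 10.5) lower, and it was the only member of any list to be called. The collagen gene Col1a1 stood at 3058 and 2853 TPM and Acta2 at 4302 and 5067. The fibroblast and matrix median was 0.29, percentile 100, with no member called. Several leading genes have close paralogs or overlap other genes: Tpm3-rs7 (5.52), Serpina3i (5.13), Il11ra2 (3.62) and the antisense Slmapos2 (2.40) among the higher, and AA465934 (-4.41), Dynlt1a (-2.16) and the antisense Hotairm1 (-2.15) among the lower. With 5 TPM added in place of 1, Pianp, Serpina3n, Slmapos2, Dynlt1a and Hotairm1 fell under 4-fold. Auts2 was lower at 5.58 against 56.95 TPM, but its counts were 80 and 89, and with CPM the log2 ratio was 0.0145.

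The brain regions together held 1732 genes higher and 171 lower than in the MEF libraries and the library labelled R1 ESC, the last of which had few pluripotency transcripts. Snap25, a core protein of synaptic vesicle fusion (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428), stood at 3295, 2748 and 2634 TPM in cerebellum, cortex and hippocampus and at most 0.56 in the others, 4703-fold (1620.0 to 22971) higher. Stmn3 was 2376-fold (423 to 93312) higher, complexin 1 (Cplx1) at least 569.8-fold, synaptophysin (Syp) 729-fold (202 to 6043) and Sncb at least 256-fold. Myelin basic protein (Mbp, ENSMUSG00000041607, chromosome 18, 82475146 to 82585637) was 741-fold (502 to 1147) higher, the prostaglandin D synthase gene Ptgds 1329-fold (237 to 52362) and the astrocyte-secreted Sparcl1 586-fold (384 to 949).

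Pan-neuronal genes were higher for 11 of 12, mature synapse genes for 12 of 14 (Vsnl1, 548, 545 and 523 TPM against at most 1.22). Oligodendrocyte genes were higher for 11 of 12 (Mag, 281, 199 and 232 against 0) and astrocyte genes for 10 of 12 (Slc1a2, 188, 637 and 691 against at most 0.90). So were 11 of 12 brain splicing regulators (Rbfox1, 161, 215 and 250.0 against at most 0.70), with no member of these lists lower. With the length trend removed 5 of the splicing regulators were higher. The 5 medians ran from 4.61 to 7.36, and each lay at percentile 99.99 or above. Haemoglobin genes were higher for 4 of 6 erythroid genes, led by Hbb-bs at 780.1, 445 and 374 TPM and 0 elsewhere; reads of these genes can be shared between copies.

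Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131, chromosome X, 20870166 to 20874735), led the lower genes at 771, 718 and 1304 TPM in ICR MEF, OG2 MEF and the library labelled R1 ESC against at most 2.62 in the brain regions, 274-fold (107 to 1006) lower. The calcium-binding genes S100a4 (126-fold, 63.7 to 292) and S100a6 (78.9-fold, 59.9 to 106), galectin-3 (Lgals3, 76.6-fold, 34.99 to 209.6), the procollagen enhancer Pcolce (50.7-fold, 37.8 to 69.7), Actg2, the mitotic gene Birc5 and Tpm2 were lower too, with Lsm7 and Hmga1b uncertain for reads shared with copies. Of the fibroblast and matrix genes 3 of 18 were lower (Col1a1, Col1a2 and Mmp2), of the p53 and senescence genes 4 of 10 (Cdkn1a, Cdkn2a, Phlda3 and Bax) and of the proliferation genes 2 of 14 (Mki67 and Tk1). With CPM, TMM factors of the TPM and the length trend removed these were 6, 11 and 13 fibroblast and matrix genes and 10, 11 and 11 proliferation genes, and with TMM factors of the counts 5 proliferation genes. Left out, the library labelled R1 ESC took the count of lower genes to 716; chance parts 3 libraries from 3 without overlap for 10% of genes. The median log2 ratio of all genes was 1.30 on the TPM scale, 0.85 with TMM factors of the counts, 0.58 with CPM, 0.15 with TMM factors of the TPM and 0.01 with the length trend removed. The share of lower genes was 8.99% on the TPM scale and 21.3%, 35.7% and 42.1% under the last 3. Here too TMM factors of the TPM and removal of the length trend bring the libraries to a common level by construction.

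Set against the 3 brain regions, the neuron library had 201 genes higher and 1956 lower. Myelin and astrocyte genes were among the lower ones: 11 of 12 oligodendrocyte genes were lower (Mag, 2.83 TPM against 281, 199 and 232) with a median of -5.76. So were 9 of 12 astrocyte genes (Slc1a3, 12.4 TPM against 960.1, 409 and 449.9) with a median of -5.02, both at percentile 0. Ptgds (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046) was 189-fold (108 to 368) lower, and the endothelial genes Cldn5 (0.26 TPM against at least 27.8), Flt1, Ly6c1 and Esam were lower. Hbb-bs had 0 counts and was at least 159.9-fold lower. Hba-a1 had 0 counts too, but its close copy Hba-a2 had 22 (18.6 TPM against 452 in hippocampus), so the 0 may reflect how shared reads were assigned. Genes of growing neurons were higher for 3 of 12, namely Tubb2b at 1760.2 TPM, Dpysl3 at 243 and Cd24a at 115, and the list's median of 1.77 lay at percentile 100. With CPM or TMM factors of the TPM 6 were higher, and 8 with the length trend removed. Mature synapse genes were lower for 5 of 14 (Shank1, 14.3 TPM against 118, 167 and 199.5) and for 3 with CPM, 2 with TMM factors of the TPM and 1 with the length trend removed.

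Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) stood at 277 TPM, 248-fold (68.3 to 2049.7) higher, and with C3, Timp1 and Lgals3 made 4 of 12 reactive glia genes, while Gfap was lower at 20.2 TPM, though not with the length trend removed. Interferon response genes were higher for 4 of 11, with Isg15 at 154 TPM against at most 5.69, Oasl2 at 67.8, Bst2 at 141 and Ifit1 at 24.01. The interferon-induced Ifi27l2a was 98.6-fold (27.02 to 819) higher. The interferon response list was not particular to neuron: its mean log2(TPM + 1) was 4.19 in neuron and 4.08 in glia, against 2.05 to 2.35 in the regions. Xist, the RNA of the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), stood at 503 TPM and at most 0.92 in the regions. The sex of the animals is not given, so this difference cannot be told apart from one of sex. Values for Lsm7, Zfp969 and Snurf, which lies within Snrpn, are uncertain for short effective lengths or shared reads. The median log2 ratio of all genes was -1.07 on the TPM scale, -0.87 with TMM factors of the counts, -0.29 with CPM, -0.16 with TMM factors of the TPM and 0.05 with the length trend removed. The share of lower genes fell from 90.7% to 68.3%, 46.9% and 58.1% under the last 3. Of these, TMM factors of the TPM and removal of the length trend bring the libraries to a common level by construction. Chance puts 1 library outside the range of 3 others for 50% of genes.

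Glia had 784 genes higher and 1026 lower than the 3 brain regions, and no member of the pan-neuronal, mature synapse or oligodendrocyte lists was higher. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) stood at 4147 TPM, 306-fold (232 to 413) higher, Tagln was 229-fold (155 to 354) higher, calponin (Cnn1) 397-fold (135 to 1918) and the insulin-like growth factor binding protein gene Igfbp2 153-fold (132 to 179) at 10579.8 TPM. Proliferation genes were higher for 12 of 14 (Mki67, 90.04 TPM against at most 1.21; Ccnd1, 1568 against at most 44.2), and p53 and senescence genes for 8 of 10 (Cdkn1a, 411 against at most 22.2). Reactive glia genes were higher for 6 of 12 (Vim, 10414 against at most 280.1) and fibroblast and matrix genes for 9 of 18 (Fn1, 1018 against at most 37.5), with Dcn of the last list lower. The 4 medians ran from 2.89 to 4.89, all at percentile 100.

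The astrocyte list split in glia: Aldh1l1 at 244 TPM and Sox9 at 94.4 were higher, S100b at 6.02, Gjb6 at 0 and Slc1a2 at 32.98 were lower, and Gfap at 1492 against 204, 169 and 408 was not called. The median was -0.05, 0.08 with CPM, 0.27 with the length trend removed and -0.14 and -0.13 without cortex and without hippocampus. Olig1 was higher at 631 TPM and Sox10 lower at 0, and no microglia gene was called (Cx3cr1, 41.7 TPM against 9.95, 44.3 and 33.6; median 0.94, or 0.43 without cerebellum). Pan-neuronal genes were lower for 10 of 12, mature synapse genes for 12 of 14 and oligodendrocyte genes for 10 of 12. The medians were -5.97, -5.45 and -5.98, all at percentile 0. Snap25 was 3608-fold (1401 to 13174) lower, Cplx1 at least 569-fold, Mbp 633-fold (443 to 939) and Hba-a2 at least 140.4-fold. The median of all genes moved from -0.17 to 0.00 with CPM, and the chance share for 1 library against 3 is again 50%. Elobl, which met the rule at 214 TPM, has a close copy and is uncertain.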

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

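The tests with TMM factors of the TPM and with the length trend removed were chosen after seeing the data, and the others before. No paired analysis was possible because each group has 1 library. The 18 counts of higher and lower genes stayed within 1.5 times with 0.1 TPM added and with TPM rescaled without haemoglobin genes. Gene lists stayed inside, above or below the central 95% of the random lists, as in the main setting, for 310 of 330 with 0.1 TPM added, 323 of 324 without haemoglobin genes, 322 of 329 with TMM factors of the counts, 303 of 329 with CPM, 315 of 328 with TMM factors of the TPM, 308 of 328 with the length trend removed, 306 of 330 with counts thinned and 317 of 330 with 5 TPM added. Of 96 named genes with an interval from counts, the log2 ratio stayed within it for 91 with 0.1 TPM added, 96 without haemoglobin genes, 89 with TMM factors of the counts, 77 with CPM, 73 with TMM factors of the TPM, 73 with the length trend removed, 95 with counts thinned and 44 with 5 TPM added. The other 32 named genes had no such interval. The floor of 1 TPM leaves the ratios of named genes unchanged, and lists were not run with it. Depth limits what can be seen below about 0.461 to 0.943 TPM, the level worth 3 counts on a gene of 2000 bases. With levels at 0 counts set to 3 counts, the list median that moved most did so by 1.86 log2 units.

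With 5 TPM added in place of 1, the counts that moved by over 1.5 times were neuron vs glia 2231 lower (from 3412), cerebellum 152 higher (from 264) and 214 lower (from 353), cortex 24 higher (from 57) and 4 lower (from 7) and hippocampus 13 higher (from 35) and 3 lower (from 14). The others were R1 ESC label vs MEFs 2485 lower (from 4064), ICR vs OG2 MEF 22 higher (from 38) and 8 lower (from 13), neuron vs regions 907 lower (from 1956) and glia vs regions 518 higher (from 784). With a floor of 1 TPM, the counts that moved by over 1.5 times were cortex 109 higher (from 57) and 23 lower (from 7), hippocampus 79 higher (from 35) and 52 lower (from 14) and ICR vs OG2 MEF 93 higher (from 38) and 41 lower (from 13). With TMM factors of the counts, the counts that moved by over 1.5 times were R1 ESC label vs MEFs 764 higher (from 409) and brain vs non-neural 284 lower (from 171). With CPM, the counts that moved by over 1.5 times were cortex 4 lower (from 7) and R1 ESC label vs MEFs 886 higher (from 409). The others were ICR vs OG2 MEF 6 lower (from 13), brain vs non-neural 401 lower (from 171) and neuron vs regions 482 higher (from 201) and 1039 lower (from 1956). With counts thinned, the counts that moved by over 1.5 times were cortex 14 lower (from 7), hippocampus 54 higher (from 35) and 28 lower (from 14) and ICR vs OG2 MEF 21 lower (from 13). With TMM factors of the TPM, the counts that moved by over 1.5 times were neuron vs glia 1920 higher (from 1163) and 2050 lower (from 3412) and hippocampus 21 higher (from 35) and 8 lower (from 14). The others were R1 ESC label vs MEFs 1677 higher (from 409) and 1721 lower (from 4064), brain vs non-neural 1035 higher (from 1732) and 574 lower (from 171) and neuron vs regions 689 higher (from 201) and 608 lower (from 1956). With the length trend removed, the counts that moved by over 1.5 times were neuron vs glia 1792 lower (from 3412) and R1 ESC label vs MEFs 1314 higher (from 409) and 1061 lower (from 4064). The others were brain vs non-neural 769 higher (from 1732) and 559 lower (from 171) and neuron vs regions 400 lower (from 1956). A larger added value shrinks ratios and a lower floor admits more genes by construction. TMM factors of the TPM and removal of the length trend bring the libraries to a common level by construction, which tends to even the higher and lower counts. For the other settings the cause was not tested.

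With 1 library left out at a time, the counts ranged as follows: cerebellum lower 497 to 564 (from 353), cortex higher 92 to 564 (from 57), cortex lower 50 to 341 (from 7), hippocampus higher 50 to 497 (from 35), hippocampus lower 92 to 376 (from 14) and brain vs non-neural lower 183 to 716 (from 171). A side with fewer libraries has fewer conditions to meet, so counts rise by construction.

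Some list medians changed sign with 1 region left out. In cortex they ranged over -0.60 to 2.45 (from 1.14) for glutamatergic forebrain and -3.35 to 0.40 (from -1.37) for Purkinje genes, with the changed sign without cerebellum, and -2.62 to 0.92 (from -1.09) for hippocampal genes, changed without hippocampus. In hippocampus they ranged over -0.49 to 2.44 (from 0.61) for GABAergic, -4.84 to 0.37 (from -2.45) for granule neuron, -0.27 to 3.36 (from 1.28) for cortical neuron and -0.39 to 0.86 (from 0.34) for immediate early genes, changed without cerebellum. Striatal genes there ranged over -3.42 to 1.02 (from -1.26), changed without cortex. These follow from the reference, which is then 1 region. Many list medians moved by over 1.5 times with the length trend removed. Among them were, against the MEFs in the library labelled R1 ESC, -3.41 (from -5.35) for fibroblast and matrix, -2.69 (from -4.59) for imprinted, -0.10 (from -2.03) for proliferation and 3.71 (from 1.94) for naive pluripotency genes. Others were -3.16 (from -5.02) for astrocyte and 2.92 (from 1.77) for immature neuron genes in neuron against the regions, 2.99 (from 4.61) for brain splicing regulators in brain and 0.12 (from 0.29) for fibroblast and matrix genes between the MEFs. With CPM the log2 ratio of Auts2 between the MEF libraries was 0.0145 (from -3.14), since CPM has no length term.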

Other observations

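HOX genes, which mark position along the body axis, set the fibroblasts apart from all brain-derived libraries. Hoxb9 stood at 30.02 and 36.8 TPM in ICR MEF and OG2 MEF, Hoxa10 at 28.99 and 26.4 and Hoxa5 at 18.6 and 25.1. In cerebellum, cortex, hippocampus, glia and neuron no HOX gene of the anterior or posterior list exceeded 0.73 TPM. In the library labelled R1 ESC Hoxc9 stood at 22.3 TPM, above 7.86 and 9.51 in the MEFs, while Hoxb9 was at 1.00. Of 24 imprinted genes 4 were higher and 6 lower in neuron than in glia (5 and 4 with the length trend removed), with a median at percentile 18.8. Cerebellum had 1 higher and 1 lower, and cortex and hippocampus had 0. H19 stood at 4622 and 5859 TPM in the MEFs and at most 25.9 in the brain-derived libraries, whereas Snrpn stood at 784, 759 and 829.6 TPM in the brain regions and 548 in neuron against 67.2 in glia. Neuronatin (Nnat) was at 1617 TPM in neuron and 55.6 in glia, and Mest at 769 TPM in glia and 7.99 in neuron.

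Among subunits of the BAF chromatin remodelling complex that change as neurons form, 1 of 4 neuronal ones was higher and 2 of 5 progenitor ones were lower in neuron than in glia, with medians at percentiles 97.99 and 18.03. Of the neuronal subunits up to 3 were higher under other scalings. Actl6b stood at 149.8 TPM in neuron and 81.1 to 123 in the brain regions and had no reads in glia, the MEFs and the library labelled R1 ESC, and the progenitor subunit Actl6a was at 6.42 TPM in neuron and 62.03 in glia. Ptbp1, a splicing repressor that falls as neurons form, was at 7.76 TPM in neuron, 252 in glia and 314 and 288 in the MEFs. Uhrf1, which brings Dnmt1 to replicated DNA, stood at 46.8 TPM in glia, 41.5 and 39.7 in the MEFs and 28.2 in the library labelled R1 ESC, and at most 1.16 in neuron and the brain regions. Xist stood at 503 TPM in neuron, 206 in the library labelled R1 ESC and 21.2 and 16.8 in the MEFs, from 1413, 392, 848 and 790 counts. Its effective length differed between these libraries, so the TPM values are uncertain. In glia it stood at 0.13 TPM and in the brain regions at no more than 0.92, and the sex of the animals is not given. The Y-linked Ddx3y stood at 5.78, 7.08, 22.9 and 7.95 TPM in neuron, the library labelled R1 ESC, ICR MEF and OG2 MEF and 57.3, 40.9 and 39.4 in cerebellum, cortex and hippocampus.

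The tests of fibroblasts and of carry-over on the fibroblast list, of glia in the neuron preparation and of choroid plexus tissue were written before the data were examined; all other tests were chosen after seeing the values.

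The library labelled R1 ESC held 12 of 21 naive pluripotency genes at no more than 3 counts and held low levels of fibroblast transcripts. Over the 18 genes of the fibroblast and matrix list its level was a median of 2.10% of the MEF level with an interquartile span of 1.63 log2 units. That span met the limit set beforehand for 1 share of feeder fibroblasts. The full range of the log2 ratio was -8.01 to -2.96, so 1 share describes the middle of the list and not every member. Over 105 genes with at least 100 TPM in both MEFs and 20-fold over each brain region (a stricter level, also looked at beforehand, gave a span over 3 too) the span was 3.51, from 1.95% to 22.2% of the MEF level. This is wider than the limit set for fibroblasts at 1 share as the only source. The library's own expression would widen that span, and is itself a source other than fibroblasts. The fall of its ratio to the MEFs with transcript length, 1.78 log2 units over 8 bins, would widen it too. Timp1 and Pcolce, which meet the rule for these genes, stood at 1304 and 839 TPM. The MEFs had 771 and 718 TPM of Timp1, and 721 and 716 of Pcolce. Fibroblasts at a share near 2.10% fall far short of those levels, so for Timp1 and Pcolce they were not the only source. For the other genes the part of the length trend in the span was not tested, and the question is not settled. Carry-over in equal shares from brain and MEF libraries was excluded, with 50 brain genes 17.9-fold below the fibroblast share (16.2-fold when ranked against the MEFs alone, a ranking that does not favour genes low in this library), while carry-over from the MEF libraries alone was not tested. For members under 1500 bases the test went against loss of long transcripts, since 1 of those 6 had more than 3 counts. It does not exclude that cause, as the median ratio to the MEFs was already -1.08 in the bin at 1274 bases. For longer members with few counts that test cannot tell, as it did not include them. Depth was excluded for the list, since 3 counts were worth a median of 0.599 TPM. A mislabelled sample stays open, with 3 of 21 members higher than in both MEFs, and differentiation was not tested. That test used pluripotency genes alone. It left aside Aldh3a1, Nccrp1 and Cnfn, at 405, 163 and 127 TPM in this library and 0 in both MEFs. Hoxc9, above both MEFs, and Xist, with 392 counts, were not part of it either.

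The cortex library held choroid plexus and striatal transcripts. Of 8 choroid plexus and ependyma genes at 5 TPM or more, 7 were above cerebellum and Foxj1 was below it (-0.93), with a lowest quartile of 1.23 and a median of 2.87 log2 units, which leaves choroid plexus tissue in the dissected piece open. All 11 striatal neuron genes were above hippocampus with a lowest quartile of 3.02. That value restates the list result that prompted it, and striatal tissue in the cortex piece stays open. Expression of the same genes by cortical cells was not tested.

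More genes were lower than higher in neuron against glia and in the library labelled R1 ESC against the MEFs. From the shortest to the longest of 8 length bins the median log2 ratio fell by 2.14 in the first (0.40 to -1.74) and by 1.78 in the second (-0.35 to -2.13), consistent with loss of long transcripts. Leaving ribosomal protein genes out of the TPM total removed 18.95% of the median ratio in the first (-0.85 to -0.69) and 28.5% in the second (-2.02 to -1.44), so their share of TPM is excluded as the whole cause. Shorter transcripts expressed by the cells themselves would give the same trend, and no biological explanation was tested.

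Over 16 astrocyte and reactive glia genes the neuron library stood at a median of 3.34% of the glia level, with an interquartile span of 2.48 log2 units. Levels under 3 counts were set to 3 counts in the carry-over, glia, choroid plexus, striatal and MEF-enriched tests. The 10 splits of the brain regions and the non-neural libraries into 3 and 3 are too few for a share under 0.05: the real split gave 1903 genes and the highest other 15, so that 1 of the 10, the real split itself, reached its count.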
